A study of Mus musculus with 4 samples.

How the data were processed

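Live CD4+ TCRβ+ YFP+ cells of the spleen (steady state) and of the cervical draining lymph node (LN, 1 day after oxazolone) were sorted from ICOS WT and ICOS FC mice at more than 95% purity, and 10x Genomics 3' gene expression libraries were made with version 3.1 chemistry, per the labels' protocols. There were 4 libraries, 1 per group, and the labels give 12000 cells as prepared without saying whether per library; the tables held 10912 spleen cells and 3963 LN cells. Per the submitters' processing notes, Cell Ranger 4.0.0, R 3.6.1, Seurat 3.0 and the mouse build GRCm38.p6 (mm10) were named; the roles of these tools, the gene annotation and any removal of doublets are not given in the sources used here. The deposited expression values, 1 table per tissue over 22056 genes, are the natural log of 1 plus UMIs per 10000 UMIs of a cell, per the values themselves. The deposited cell table gives each cell's UMI count and number of genes detected, the percent of mitochondrial counts, S and G2M phase scores, cluster numbers and a genotype column. Its entries read Control and KO, with a prefix for steady state in the spleen table; Control was taken as ICOS WT and KO as ICOS FC, a match made from the words alone. The phase scores, phases and UMAP coordinates were not used for any comparison. The deposited cells had at least 503 and 500 UMIs and at most 9.99% mitochondrial counts in the spleen and LN tables, and no further filter was applied here. An earlier cluster numbering in the spleen table ran to 13 with 4 numbers absent, and in the LN table to 7 with 1 absent; the reason is not given in the sources used here. T cell receptor and immunoglobulin segments were not analysed here.

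Each deposited log value was turned back into UMIs by inverting the log and multiplying by the cell's deposited count. Within 0.001, 100% of 17846401 spleen values and 8798056 LN values came out whole, and all 10912 and 3963 cells equalled their deposited totals and numbers of genes detected. These counts were summed over the cells of each library and divided by the library total to give counts per 1000000 (CPM). Because every group was 1 library, no test was run; the log2 ratio of CPM, ICOS FC over ICOS WT, is given with an exact conditional Poisson interval at 95%, and shares of cells with an exact (Clopper-Pearson) binomial interval, and these cover counting error only. The Poisson intervals treat each UMI as independent and leave out the sampling of cells. They are too narrow for a gene whose UMIs sit in few cells. A value within a cluster needed at least 50 cells of each library. A gene counted as higher or lower by a rule of size: at least 20 CPM in a library, a ratio of at least 1.5-fold, and an interval clear of equality. For LN against spleen the ratio had to reach 2-fold under both labels. Independent lists of the same lengths would share the product of their lengths divided by the number of genes compared, which is given beside each overlap.

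The groups, the rules of size, the 31 gene lists, the rule for named genes and the processing alternatives were fixed before the data were examined. Named genes were Icos and Foxp3, the 12 highest and 12 lowest genes per tissue ranked by the interval bound nearest equality, up to 4 members per list by the same bound and any list member with at least 100 CPM, and the 10 highest and 10 lowest genes of the LN against the spleen with the same sign under both labels. Some genes that the rule names are not reported here. Receptor segments, haemoglobin, mitochondrial and sex-linked genes and Gm or Rik gene models stayed out of the ranking. As groups, mitochondrial genes summed to 42672 and 41611 CPM in the spleen and 37931 and 35050 CPM in the LN with 0 past the rule, and 2 LN gene models, A430078G23Rik and Gm47283, were higher. A list was described by its members with at least 5 CPM in a library and, from 3 members on, by the median log2 ratio with 0.5 CPM added to each level. Its interval came from 1000 Poisson redraws, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. A median outside the central 95% stands apart in these libraries. The random lists were drawn once, with library totals and all cells, and were not redrawn for the alternatives. A median called inside its range under an alternative is set against that first range. Members counted as higher or lower at 1.5-fold with an interval clear of equality, without the minimum of 20 CPM. Members that did not pass are called between. The lists were written by hand from general knowledge, and some genes, such as Ctla4, Lag3 and Il2ra, are members of several. They were B cell, plasma cell, myeloid, CD8 T and NK, gamma-delta T, erythroid, platelet, conventional CD4 T, and stroma and endothelium markers for cells that a sort might let through, and the Treg, signalling, metabolic and receptor lists named with the results.

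The deposited clusters were kept and named X-like from markers fixed with the lists: a name needed at least 3 detected markers and a marker among the 10 genes highest by fold, and no conflict with another list. To compare cluster sizes without the genes that differ, cells were clustered again with Leiden (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9) on 2000 variable genes, 30 principal components, 15 neighbours and resolution 0.5. This was done without Icos, without every gene differing by 1.25-fold at 5 CPM or more, and without those differing when clusters are weighted equally, and each new cluster was matched to the deposited cluster that gave the largest share of its cells, at times a minority of them. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs, which left out 89 and 155 spleen cells and 69 and 59 LN cells. No doublet caller was run, and the cells with most UMIs were left out as an alternative. Alternatives were TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors over genes with a summed count of at least 10, a total without ribosomal and mitochondrial genes, cells with at least 1000 UMIs, cells under 5% mitochondrial counts, no top 5% of cells by UMIs, only cells with a Foxp3 UMI and none of Cd79a, Lyz2 or Cd8a, the mean of each cell's CPM, clusters weighted equally, thinned cells, minimums of 5 and 50 CPM (20 CPM for list members), and Leiden clusters without Icos. Added after seeing the data were the counts without doubtful clusters (spleen 4, low in Foxp3, and LN 6 and 7), the other 2 clusterings, the overlap counts under each setting, and the settings for the LN against the spleen.

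The comparison was tested on simulated libraries with known folds, drawn as independent Poisson counts from means shared by both libraries. The intervals make the same assumption, so this checks the computation only. It says nothing about variation between animals or libraries, or about genes that move together. Of 50 genes per fold, the rule of size recovered 0 in the spleen and 1 in the LN at 1.3-fold, below the rule, and 50 at each of 2-, 3- and 4-fold in both tissues, among 5032 and 5398 genes, with 0 unchanged genes called. Intervals covered the true ratio for 95.3% and 94.8% of genes. Unchanged lists fell outside the central range in 5.45% of 220 spleen draws and 6.67% of 240 LN draws, and all 22 and 24 lists moved by 0.5 were found. Coordinates are from GENCODE M21 on GRCm38, which gave positions for 21838 of the genes by symbol. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and in R 4.3.3, with random seed 7.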

Results

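Gene expression was measured in single CD4+ T cells from mice of the C57BL/6 strain, sorted as live cells carrying CD4, TCRβ and YFP (yellow fluorescent protein) at more than 95% purity. The cells are regulatory T (Treg) cells by their labels. Treg cells are CD4+ T cells that restrain immune responses and depend on the transcription factor Foxp3. The labels name ICOS WT mice and ICOS-deficient mice titled ICOS FC. ICOS is a costimulatory receptor of the CD28 family, induced on activated T cells and present on many Treg cells. Spleen cells were taken at steady state, and cervical draining lymph node (LN) cells were taken 1 day after challenge with oxazolone, a hapten that provokes contact hypersensitivity in the skin. Each of the 4 groups was 1 library, so the differences have no replicate check, nothing was tested across animals, and every interval covers counting error only. In the spleen, 4995 cells with 27183614 UMIs (unique molecular identifiers, each standing for a captured transcript) came from the library labelled ICOS WT and 5917 cells with 28256866 UMIs from the library labelled ICOS FC. The LN libraries held 1897 cells with 15045805 UMIs for ICOS WT and 2066 cells with 17330489 UMIs for ICOS FC. Median UMIs per cell were 5044 and 4361 in the spleen and 6591 and 6789 in the LN. A count of 0 allows up to 0.110 and 0.106 counts per 1000000 UMIs (CPM) in the spleen libraries and up to 0.199 and 0.173 CPM in the LN libraries, taking 3 counts per library as the limit. In the comparisons of the libraries labelled ICOS WT and ICOS FC, values given as a pair put ICOS WT before ICOS FC, log2 ratios are ICOS FC over ICOS WT, and brackets hold 95% counting intervals.

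Icos, the gene targeted in the design, was at a higher level in the library labelled ICOS FC in both tissues. In the spleen, 3040 and 7284 Icos UMIs gave 112 and 258 CPM, a 2.31-fold difference with a log2 ratio of 1.205 [1.14, 1.27]. In the LN, 9005 and 16080 UMIs gave 598.5 and 927.8 CPM, a 1.55-fold difference with a log2 ratio of 0.63 [0.60, 0.67] (0.51, under 1.5-fold, with clusters weighted equally). The gene lies on chromosome 1 at 60977927 to 61000320 (GRCm38, GENCODE M21). The direction goes against a loss of the transcript in the libraries labelled ICOS-deficient, so they are called by their labels throughout. The part of the gene that was deleted is not given in the sources used here, and a 3' tag outside it checks nothing. An exchange of the labels is therefore not excluded, and it would turn the direction, with respect to genotype, of every ratio, list median and cluster share between the labels. Icos was higher in the library labelled ICOS FC, with intervals clear of equality, in 5 of the 6 spleen clusters with enough cells, at log2 ratios of 0.86, 1.37, 1.05, 0.73 and 1.02 in clusters 0, 1, 2, 3 and 5. In spleen cluster 4 it was low in both libraries, at 33.5 and 37.7 CPM (0.17 [-0.19, 0.53]). The LN clusters 0 to 5 had Icos ratios of 0.45, 0.68, 0.80, 1.75, 0.58 and 0.56, and clusters 6 and 7 had 0.20 [-0.12, 0.51] and 0.23 [-0.01, 0.47]. With every cell thinned to 2000 UMIs, 16.4% and 27.2% of spleen cells and 42.2% and 53.6% of LN cells had an Icos UMI. Without thinning these shares were 29.9% and 39.9% in the spleen and 60.5% and 71.0% in the LN, beside 15.9% and 14.8% in spleen cluster 4, whose cells held 5492 and 4845 UMIs at the median.

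Foxp3, the lineage factor of Treg cells (X chromosome, 7573644 to 7595245), was at 53.2 and 59.0 CPM in the spleen (0.15 [0.05, 0.25]) and at 72.2 and 70.7 CPM in the LN (-0.03 [-0.15, 0.09]). The LN value turned to 0.01 with TMM factors, 0.02 with DESeq2 factors, 0.00 in cells under 5% mitochondrial counts and 0.04 in thinned cells. A Foxp3 UMI was seen in 20.8% [19.7, 21.9] and 21.8% [20.8, 22.9] of spleen cells and in 37.3% and 38.9% of LN cells, and after thinning in 9.85%, 11.3%, 14.5% and 14.8%. Spleen cluster 4 set the background, with a Foxp3 UMI in 1.22% and 2.44% of its cells. That cluster was low in Foxp3 in both libraries, at 4.03 CPM against 64.2 CPM in the remaining spleen cells, although every cell came from the same sort.

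**Figure D1:**
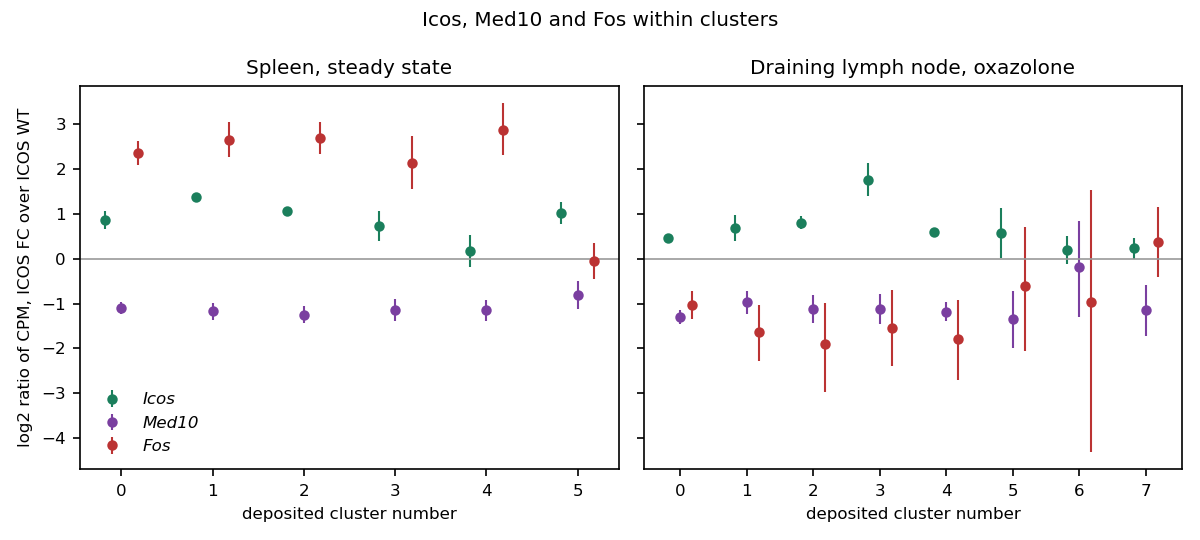
Log2 ratios of CPM, ICOS FC over ICOS WT, for Icos, Med10 and Fos within each deposited cluster (x axis, cluster number) of the spleen and LN libraries, 1 library per group; points are ratios of summed UMIs and bars are 95% counting intervals. Icos is near 0.17 in spleen cluster 4, where Med10 stands at -1.15, and Fos is at -0.05 in spleen cluster 5 and above 2 in spleen clusters 0 to 4.

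The first comparison asked how spleen Treg cells at steady state differed between the libraries labelled ICOS WT and ICOS FC. Transcripts of the AP-1 transcription factor subunits were higher in the library labelled ICOS FC: Fos was at 16.3 and 75.7 CPM (442 and 2140 UMIs, 4.66-fold, log2 2.22 [2.07, 2.37]), Fosb at 9.93 and 29.3 CPM (1.56 [1.36, 1.76]) and Jun at 82.5 and 185 CPM (1.16 [1.09, 1.23]). Lag3, an inhibitory receptor that binds MHC class II, was at 15.3 and 49.05 CPM (1.68 [1.52, 1.85]). Med10, a subunit of the Mediator complex on chromosome 13 (69802395 to 69816104), was 2.17-fold lower, at 152 and 69.9 CPM (-1.12 [-1.19, -1.04]). Pdcd1, which encodes the inhibitory receptor PD-1, was at 46.8 and 22.5 CPM (-1.05 [-1.19, -0.92]). Among 5105 genes with at least 20 CPM in a library, 30 were at least 1.5-fold higher and 13 at least 1.5-fold lower in the library labelled ICOS FC, with a median log2 ratio of -0.02. These counts describe the libraries and carry no test.

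Of the other spleen genes at the top of the ranking, Ly6k, a Ly6 family surface protein, was at 5.85 and 20.3 CPM (1.80, and 2.39 in thinned cells). Cxcl10, a chemokine that binds Cxcr3, had a log2 ratio of 1.51. Prg4, which encodes lubricin, was at 9.90 and 25.7 CPM (1.37 [1.17, 1.58]). Bhlhe40, a basic helix-loop-helix repressor, had 1.299, and 2.10 in the cells with a Foxp3 UMI. Ppp1r15a, a phosphatase subunit that acts on eIF2α, was at 26.3 and 62.8 CPM (1.26) and Rgs2, a regulator of G protein signalling, at 15.5 and 34.6 CPM (1.16). AC149090.1, a gene on the unplaced scaffold JH584304.1, was at 62.6 and 129 CPM (1.05); tags of unplaced copies are uncertain. On the lower side, Penk, the precursor of enkephalin peptides, had a log2 ratio of -1.04, Ddit4, an inhibitor of mTORC1, was at 179.9 and 99.1 CPM (-0.86), and S100a4, a calcium-binding protein, was at 255 and 145 CPM (-0.81). Thy1, a surface glycoprotein of T cells, was at 257 and 155 CPM (-0.73), and Nkg7, a protein of cytotoxic granules, at 51.6 and 32.0 CPM (-0.69). Nrn1, Dapl1, Il18r1 and Nrip1 had ratios of -0.73, -0.69, -0.61 and -0.56, and Rnaset2a, whose tags are uncertain because of its near-identical copy Rnaset2b, had -0.60. TMM and DESeq2 factors each gave 36 higher and 9 lower genes, 30 and 9 of them shared with the count above. Without cluster 4, a setting chosen after seeing the data, 32 were higher and 20 lower, of which 28 and 13 were shared.

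**Figure D2:**
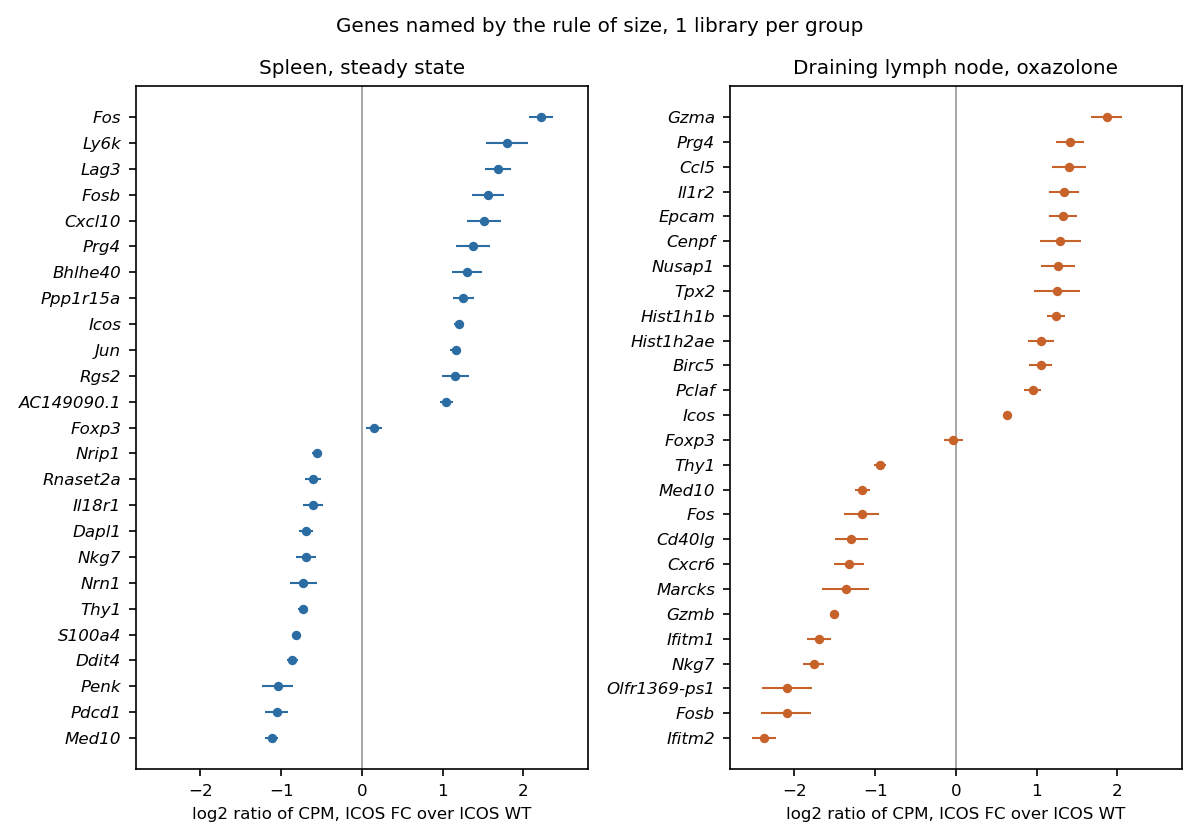
Log2 ratios of CPM, ICOS FC over ICOS WT (x axis), for the genes named by the rule of size in the spleen and the LN, 1 library per group; points are ratios of summed UMIs and bars are 95% counting intervals. Fos stands at 2.22 in the spleen and -1.17 in the LN, and Ifitm2 stands at -2.37 in the LN.

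By the fixed gene lists, the dissociation stress genes, immediate early and heat shock genes that tissue handling can induce, stood highest in the spleen library labelled ICOS FC. Of 12 measured members, 5 were at least 1.5-fold higher, 0 lower and 7 between, and the intervals of all 12 lay above equality. The list median was 0.51 [0.47, 0.57], where 95% of random lists of matched expression lay from -0.08 to 0.05. Junb was at 314 and 617 CPM, Dusp1 at 34.6 and 72.4 CPM, Zfp36 at 97.3 and 145 CPM and Hspa8 at 1552 and 1911 CPM. Suppressive molecules had 3 higher, 1 lower and 8 between of 12, with a median of 0.35 [0.25, 0.39] against a random range of -0.11 to 0.06. Il10, an anti-inflammatory cytokine, was at 1.18 and 6.87 CPM (2.54 [1.999, 3.13], and 1.89 in cells with a Foxp3 UMI), Fgl2 at 7.50 and 19.995 CPM (1.41) and Ctla4, an inhibitory receptor of the CD28 family, at 103 and 139 CPM (0.43). Treg identity genes had 0 of 14 past 1.5-fold, with 8 intervals above and 1 below equality and a median of 0.15 [0.09, 0.18] against -0.08 to 0.05. Izumo1r was at 527 and 680.2 CPM, Socs2 at 36.2 and 49.0 CPM, Capg at 182 and 215 CPM and Gpr83 at 67.6 and 54.9 CPM.

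Cholesterol synthesis genes were lower in the spleen library labelled ICOS FC: 0 of 13 passed 1.5-fold, but 11 intervals lay below equality and 0 above, with a median of -0.23 [-0.36, -0.20] against -0.13 to 0.06. Idi1 was at 26.6 and 18.4 CPM, Scd2 at 21.6 and 14.97 CPM, Cyp51 at 24.3 and 17.2 CPM and Sqle at 12.5 and 9.06 CPM. Follicular Treg genes had 0 higher, 2 lower and 5 between of 7 (median -0.30 [-0.45, -0.09], random range -0.14 to 0.09). Cxcr5, the receptor for entry into B cell follicles, was at 10.9 and 5.84 CPM, Bcl6 at 9.71 and 7.36 CPM and Sh2d1a at 184 and 225 CPM. That list lay inside the random range in cells under 5% mitochondrial counts (-0.05), in cells with a Foxp3 UMI (-0.07) and over members with at least 20 CPM (-0.01). The minimum of 20 CPM leaves out Cxcr5 and Bcl6, and the range is that of all 7 members. Th1-type genes had 0 higher, 1 lower (Nkg7) and 3 between of 4 (-0.24, range -0.16 to 0.13), with Ccl5, a chemokine, at 136 and 197 CPM. The Th1-type median was inside the range with the total without ribosomal and mitochondrial genes (-0.14), in cells under 5% mitochondrial counts (-0.16) and over members with at least 20 CPM (-0.13). Conventional CD4 T cell markers had 0 higher, 1 lower (Dapl1) and 2 between of 3 (-0.37, range -0.17 to 0.12). The median was 0.08 with the total without ribosomal and mitochondrial genes. That total moved spleen ratios by a median of only 0.002. This median and the Th1-type one therefore moved because further members reached 5 CPM. Cd40lg, the ligand of CD40, was at 27.0 and 20.7 CPM and Tnfsf8 at 61.4 and 91.3 CPM. The Foxp3-low cluster 4, in which Cd40lg was at 57.7 CPM, held 14.8% and 11.1% of the cells.

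Migration receptors had 0 higher, 2 lower and 16 between of 18 (-0.12, range -0.09 to 0.05; -0.01 in cells with a Foxp3 UMI), with Ccr6 at 8.98 and 5.73 CPM, Ccr2 at 22.6 and 16.0 CPM and Itgb1 at 189 and 248 CPM. TCR-induced early genes, which T cell receptor signalling switches on, had 1 higher, 0 lower and 9 between of 10. Their median of -0.13 lay just past a range of -0.12 to 0.06, was inside it under 5 alternatives and turned to 0.02 without the 5% of cells with most UMIs. The 5 include TMM (-0.11) and DESeq2 factors (-0.10), which moved the ratios of all genes by a median of 0.02. The range would move with them, so these values do not bring the list closer to other genes. Irf4 was at 11.3 and 17.2 CPM, Cd69 at 203 and 264 CPM and Egr3 at 16.4 and 12.2 CPM (-0.43, and -1.48 in cells with a Foxp3 UMI). Proliferation genes had 0 of 14 past 1.5-fold and a median of 0.15 (range -0.11 to 0.05), which turned to -0.07 without the 5% of cells with most UMIs, -0.05 as the mean of each cell's CPM and -0.06 in thinned cells. The other spleen lists lay inside their random ranges. Effector Treg genes had 4 higher, 1 lower and 12 between of 17 (median 0.03), with Prdm1 at 8.79 and 16.1 CPM and Batf at 68.1 and 103.5 CPM. Costimulatory and inhibitory receptors had 2 higher, 1 lower and 11 between of 14 (-0.04). ST2 tissue Treg and Th2-type genes had 1 higher and 4 between of 5 (0.06), with Nfil3 at 6.33 and 14.05 CPM (1.15, and 1.98 in cells with a Foxp3 UMI). NF-kB genes had 1 higher and 13 between of 14 (0.03), with Tnfaip3 at 22.0 and 39.2 CPM. Interferon response genes had 1 higher (Ifit3) and 13 between of 14 (-0.05). IL-2 and STAT5 genes had 1 higher and 11 between of 12 (0.01), with Pim1 at 215 and 328 CPM, and apoptosis genes 1 higher (Pmaip1) and 10 between of 11 (0.05). No member passed 1.5-fold among the 12 resting Treg genes (-0.05), 12 FoxO and Klf2 targets (-0.01), 14 glycolysis genes (-0.01), 21 oxidative phosphorylation genes (-0.03), 80 ribosomal protein genes (0.02) and 3 CD8 T and NK genes (0.07). Lists with fewer than 3 measured members are given as summed CPM: B cell 81.3 and 81.75 (Cd79b at 10.96 and 19.6 CPM, 0.84 [0.64, 1.05], and Cd74 at 59.9 and 55.2 CPM, -0.12 [-0.22, -0.01]), Th17-type 54.9 and 44.8, plasma cell 50.9 and 47.2, myeloid 119.8 and 132, erythroid 0.515 and 2.02, platelet 0.147 and 0.425, and stroma and endothelium 66.6 and 60.4. The 6 gamma-delta T genes were not analysed here.

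**Figure D3:**
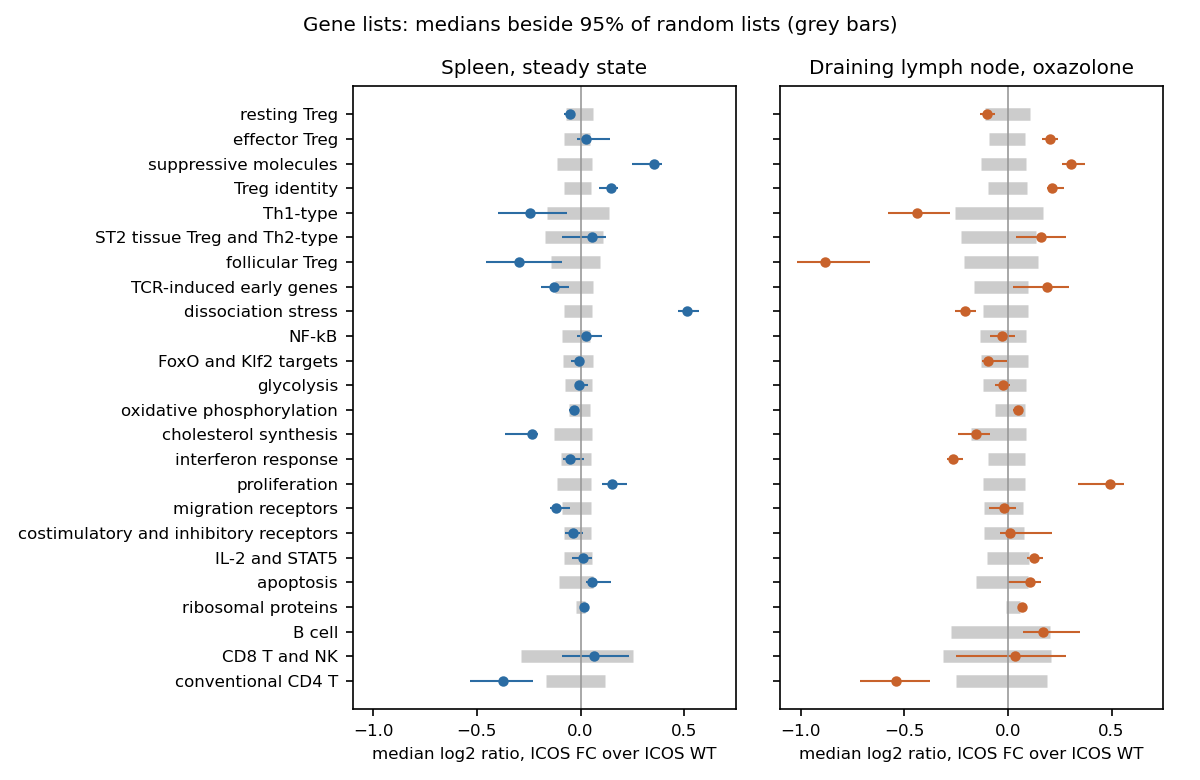
Median log2 ratio of CPM, ICOS FC over ICOS WT (x axis), of each fixed gene list with at least 3 measured members in the spleen and the LN, 1 library per group; points are medians, bars are 95% counting intervals and grey bars hold 95% of random lists. Dissociation stress genes are at 0.51 in the spleen and -0.21 in the LN, and follicular Treg genes are at -0.30 and -0.88.

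The deposited spleen clusters included a follicular Treg-like cluster (1), an effector Treg-like cluster (2), a resting Treg-like cluster (3) and an interferon response-like cluster (6), and clusters 0, 4 and 5 stayed unnamed. The interferon response-like cluster held 0.941% [0.692, 1.249] and 1.98% [1.64, 2.37] of spleen cells. Its counterpart held 0.901% and 2.08% when cells were clustered without Icos, 0.541% and 1.45% without the 562 genes that differed between the libraries, and 1.18% and 2.25% without the 539 that differed at equal cluster weights. Cluster 4 held 14.8% and 11.1%, and its counterpart 15.5% and 11.7%, 25.6% and 28.1%, and 16.3% and 12.9% in the same order, so the direction turned in the clustering without all differing genes, where the counterpart drew only 44.6% of its cells from cluster 4. The follicular Treg-like cluster held 17.1% [16.1, 18.2] and 18.8% [17.8, 19.8], and its counterpart 21.5% and 22.4%, 20.3% and 21.4%, and 20.04% and 19.99%. As deposited, the resting Treg-like cluster 3 held 10.7% [9.87, 11.6] and 15.9% [14.9, 16.8]. It had no counterpart in any of the 3 new clusterings, so its share could not be compared there. The clusterings without differing genes were added after seeing the data. Fos was higher in the library labelled ICOS FC within spleen clusters 0 to 4 (2.35, 2.63, 2.68, 2.12 and 2.85) but not in cluster 5 (-0.05 [-0.46, 0.36]).

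The second comparison asked how Treg cells of the draining LN differed 1 day after oxazolone. Ifitm2, an interferon-induced membrane protein, was 5.18-fold lower in the library labelled ICOS FC, at 131 and 25.3 CPM (-2.37 [-2.53, -2.22]). Gzmb, the cytotoxic protease granzyme B (chromosome 14, 56258838 to 56262260), had 20493 and 8312 UMIs, or 1362 and 479.6 CPM (-1.51 [-1.54, -1.47]). Nkg7 was at 123 and 36.2 CPM (-1.76 [-1.89, -1.63]) and Cxcr6, a chemokine receptor of effector T cells, at 50.1 and 20.02 CPM (-1.32 [-1.51, -1.14]). On the higher side, Prg4 was at 22.9 and 60.9 CPM (1.41 [1.24, 1.59]), Il1r2, a decoy receptor for IL-1, at 21.1 and 53.4 CPM (1.34 [1.16, 1.53]) and Epcam, an adhesion molecule, at 25.2 and 63.0 CPM (1.32 [1.15, 1.495]). Among 5506 genes, 61 were at least 1.5-fold higher and 58 lower, with a median log2 ratio of -0.03, and without cluster 6 (few UMIs per cell) and cluster 7 (CD8 T and NK-like), a setting added after seeing the data, the counts were 65 and 59, of which 59 and 56 were shared. In thinned cells the counts were 76 and 133, sharing 35 and 39.

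Several LN values depended on which cells were counted. Gzma, another granule protease, was at 19.0 and 69.3 CPM (1.87 [1.68, 2.06]). Its log2 ratio was 0.45 without the 5% of cells with most UMIs, 1.24 as the mean of each cell's CPM, 3.05 without clusters 6 and 7 and 3.66 in cells with a Foxp3 UMI. It was 3.40 [3.07, 3.75] in cluster 0 and -2.96 [-3.75, -2.25] in the CD8 T and NK-like cluster 7, in which Cd8a was at 172 CPM and Foxp3 at 37.9 CPM. Gzmb was lower in the effector Treg-like cluster 0, at 3266 and 999.5 CPM (-1.71 [-1.75, -1.66]), and in cluster 4 (-2.20 [-2.28, -2.12]), and higher in clusters 2 (0.86 [0.32, 1.40]) and 7 (2.21 [1.95, 2.47]). Ifitm1, a relative of Ifitm2 with which tags may be shared, was at 88.4 and 27.35 CPM (-1.69), with -0.79 without the 5% of cells with most UMIs, -2.39 in cells with a Foxp3 UMI and -2.91 without clusters 6 and 7. Ccl5 was at 16.7 and 43.9 CPM (1.40, and 2.68 in cells with a Foxp3 UMI). The cell division genes Cenpf, Nusap1, Tpx2 and Birc5 had ratios of 1.29, 1.26, 1.252 and 1.05, and the histone gene Hist1h1b had 1.24. As the mean of each cell's CPM these were 0.18, 0.09, 0.11, 0.29 and 0.41. Cenpf was 2.07 without the 5% of cells with most UMIs and Nusap1 0.48 in thinned cells. Hist1h2ae, whose tags are uncertain among histone copies, and Pclaf, a PCNA-binding factor, had 1.06 and 0.95. Fosb was at 28.4 and 6.64 CPM (-2.10 [-2.41, -1.80]) and Fos at 33.7 and 15.003 CPM (-1.17 [-1.39, -0.95]). Olfr1369-ps1, with uncertain tags, had -2.09 (-3.01 without the 5% of cells with most UMIs, -2.75 thinned) and Marcks, a substrate of protein kinase C, -1.36 (-0.73 thinned). Cd40lg was at 40.0 and 16.3 CPM (-1.29), and at 162 CPM in cluster 7, the CD8 T and NK-like cluster. Med10 was at 172 and 77.3 CPM (-1.16 [-1.25, -1.06]) and Thy1 at 272 and 142 CPM (-0.94).

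Proliferation genes were higher in the LN library labelled ICOS FC, with 7 higher, 0 lower and 10 between of 17 and a median of 0.49 [0.34, 0.56] against a random range of -0.12 to 0.08. Top2a, a DNA topoisomerase of dividing cells, was at 85.3 and 150.4 CPM, Stmn1 at 116 and 184 CPM, Ube2c at 42.5 and 70.5 CPM (0.73, and 1.44 without the 5% of cells with most UMIs) and the division marker Mki67 at 41.2 and 73.9 CPM (0.84). A Mki67 UMI was seen in 10.3% and 10.6% of cells, and in 3.06% and 4.43% after thinning, which left out 69 and 59 cells. The background in cluster 5 was 0 of 119 cells, which allows up to 3.05%, and 0.962% of 104 cells, at 6983 and 6318 median UMIs. Suppressive molecules had 2 higher, 1 lower (Gzmb) and 11 between of 14 (0.30 [0.26, 0.37], range -0.13 to 0.09). Lrrc32, which presents latent TGF-β, was at 90.8 and 138 CPM, Ebi3, a cytokine subunit, at 19.5 and 30.5 CPM and Lag3 at 56.8 and 81.8 CPM. Treg identity genes had 1 higher, 0 lower and 13 between of 14 (0.21 [0.19, 0.27], range -0.10 to 0.09), with Il2ra, the IL-2 receptor alpha chain, at 448 and 591 CPM, Izumo1r at 538 and 703 CPM and Ctla4 at 510.1 and 652 CPM. Effector Treg genes had 0 higher, 1 lower (Id2) and 18 between of 19 (0.20 [0.17, 0.24], range -0.09 to 0.08), with Tnfrsf4, the costimulatory receptor OX40, at 979.8 and 1381 CPM, Batf at 173 and 252 CPM and S100a4 at 660.2 and 466 CPM.

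Follicular Treg genes were lower in the LN library labelled ICOS FC, with 0 higher, 4 lower and 3 between of 7 and a median of -0.88 [-1.02, -0.66] against -0.21 to 0.14. Cxcr5 was at 19.4 and 8.42 CPM (-1.20), Bcl6, the transcription factor of follicular T cells, at 10.0 and 4.27 CPM (-1.23), Tox2 at 12.5 and 5.77 CPM (-1.11), Pdcd1 at 38.9 and 20.9 CPM (-0.90) and Slamf6 at 275 and 341 CPM. Over members with at least 20 CPM, which leaves out Cxcr5, Bcl6 and Tox2, the follicular median was -0.17. That value lay inside the random range of all 7 members. Interferon response genes had 0 of 16 past 1.5-fold but 14 intervals below and 1 above equality (-0.26 [-0.29, -0.21], range -0.10 to 0.08), with Ifit3 at 211 and 150.3 CPM, Isg15 at 748 and 600.4 CPM and Stat2 at 76.7 and 57.1 CPM. Dissociation stress genes had 0 higher, 3 lower and 9 between of 12 (-0.21 [-0.25, -0.15], range -0.12 to 0.10), with Jun at 102 and 55.2 CPM, Junb at 421 and 335 CPM and Hsp90aa1 at 529 and 690.5 CPM. Of the 12 intervals, 7 lay below and 4 above equality, and the summed level of the members was 4209 and 4222 CPM. Th1-type genes had 1 higher (Ccl5), 1 lower (Nkg7) and 3 between of 5 (-0.44 [-0.58, -0.28], range -0.25 to 0.17), with Cxcr3 at 60.6 and 43.1 CPM. Conventional CD4 T cell markers had 0 higher, 2 lower and 2 between of 4 (-0.54 [-0.71, -0.37], range -0.25 to 0.19), with Dapl1 at 42.3 and 27.4 CPM and Il2 at 12.03 and 8.60 CPM (-0.48, turning to 0.06 in cells under 5% mitochondrial counts and 0.26 in cells with a Foxp3 UMI).

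TCR-induced early genes in the LN had 0 higher, 2 lower (Egr1 and Egr3) and 8 between of 10, although their median was 0.19 [0.03, 0.30] against -0.17 to 0.10. Myc was at 62.3 and 92.5 CPM and Egr1 at 59.2 and 38.7 CPM. ST2 tissue Treg and Th2-type genes had 1 higher (Nfil3, 14.2 and 24.9 CPM) and 6 between of 7 (0.16, range -0.22 to 0.14), a median that was 0.01 with equal cluster weights and turned to -0.07 in cells with a Foxp3 UMI, -0.00 as the mean of each cell's CPM and -0.13 in thinned cells. IL-2 and STAT5 genes had 0 of 12 past 1.5-fold (0.13, range -0.10 to 0.10, and 0.09 in cells with a Foxp3 UMI), and apoptosis genes 0 of 11 (0.11, range -0.16 to 0.10). The apoptosis median lay inside the range under 4 alternatives, at 0.09 without the 5% of cells with most UMIs, 0.03 in cells with a Foxp3 UMI, 0.10 with equal cluster weights and 0.06 in thinned cells. Ribosomal protein genes had 0 of 80 past 1.5-fold, 69 intervals above and 5 below equality and a median of 0.07 against -0.01 to 0.06. The remaining LN lists lay inside their ranges. Resting Treg genes had 1 lower and 11 between of 12 (-0.10), with Igfbp4 at 157 and 96.0 CPM and Tcf7 at 148 and 100.4 CPM. Migration receptors had 3 lower and 17 between of 20 (-0.02), with Ccr2 at 136 and 77.4 CPM. Costimulatory and inhibitory receptors had 1 higher, 2 lower and 12 between of 15 (0.01), and cholesterol synthesis genes 1 lower (Scd2) and 12 between of 13 (-0.15). B cell markers had 1 higher (Cd79b, 10.9 and 22.4 CPM) and 3 between of 4 (0.17). CD8 T and NK genes had 1 higher (Gzma) and 4 between of 5 (0.03). No member passed 1.5-fold among 14 NF-kB genes (-0.03), 12 FoxO and Klf2 targets (-0.10), 15 glycolysis genes (-0.02) and 21 oxidative phosphorylation genes (0.05). The short lists had summed CPM of 83.8 and 73.6 for Th17-type, 86.3 and 106 for plasma cell, 150.7 and 166 for myeloid, 0.133 and 0.115 for erythroid, 0.399 and 0.404 for platelet, and 57.8 and 49.1 for stroma and endothelium.

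The LN follicular Treg-like cluster (2) held 20.6% [18.8, 22.5] of the cells labelled ICOS WT and 10.7% [9.40, 12.1] of those labelled ICOS FC. Its genes differed between the libraries, so cells were clustered again: without Icos its counterpart held 19.8% and 9.73%, and without the 1009 genes that differed at equal cluster weights it held 20.9% and 12.5%. Without all 1342 differing genes the counterpart held 25.3% and 25.3%, and 46.2% of its cells came from cluster 2. The other LN clusters were effector Treg-like (0), resting Treg-like (1), interferon response-like (5) and CD8 T and NK-like (7), and clusters 3, 4 and 6 stayed unnamed. As deposited, cluster 3 held 7.22% [6.10, 8.48] and 14.2% [12.7, 15.8] of the cells, cluster 6 5.22% and 3.87%, and cluster 7 3.48% and 2.76%. Clusters 3, 6 and 7 had no counterpart in the new clusterings, so their shares could not be compared there. Cluster 6 held cells of few UMIs, 1959 at the median, and cluster 4 cells of many, 12828.

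Genes were then compared between the tissues, to see whether the libraries labelled ICOS FC differed from ICOS WT in the same way in the spleen and the LN. Among 4949 genes with at least 20 CPM in a library of each tissue, 25 and 13 were higher and lower in the spleen and 29 and 30 in the LN. The 9 genes higher in both were Icos, Prg4, Cxcl10, Epcam, Il1r2, AC149090.1, Agpat4, Cd83 and Dus2, where independent lists would share 0.146, and Agpat4, Cd83 and Dus2 are named after their values were seen. The 6 genes lower in both were Med10, Pdcd1, Thy1, Nkg7, Nrn1 and Dapl1, where 0.0788 would be shared. Another 5, Fos, Fosb, Jun, Ppp1r15a and Rgs2, were higher in the spleen and lower in the LN, against 0.152 for independent lists, and 0 went the other way, against 0.0762. With clusters weighted equally 5 of the 9 remained higher in both tissues, without Icos, whose LN ratio was then 0.51, under 1.5-fold, and 6 of the 9 remained in thinned cells. Across these genes, which are not independent replicates, the log2 ratios of the tissues had a Pearson r of 0.287 and a Spearman rho of 0.279.

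The LN cells after oxazolone were also set against the steady-state spleen cells within each genotype label, a contrast in which tissue, challenge and the separately deposited tables change together. In this paragraph paired values are LN over spleen, first for ICOS WT and then for ICOS FC. Gzmb was 481-fold and 151-fold higher in the LN, and Ifitm1, with 0 UMIs in both spleen libraries, had log2 ratios whose 95% counting intervals began at 9.35 and 7.71. Gzma was 20.7-fold and 39.2-fold higher, Gcnt1, a glycosyltransferase of mucin-type glycans, 19.2-fold and 18.3-fold, and Areg, which encodes amphiregulin, 12.4-fold and 10.3-fold. The interferon-induced genes Ifitm3, Ifit3b and Ifit3 were 34.6-fold, 29.99-fold and 27.6-fold higher for ICOS WT and 13.4-fold, 11.1-fold and 9.63-fold higher for ICOS FC, and Ccna2, cyclin A2, was 11.8-fold and 14.6-fold higher. Ccl5 was 8.17-fold and 4.48-fold higher in the spleen, Sox4 4.69-fold and 6.72-fold, Frat2 2.39-fold and 4.81-fold, Ramp1 2.86-fold and 3.37-fold, and the integrin chain Itga4 3.14-fold and 2.65-fold. Atp1b1, Bbc3, Pik3ip1, Lman2l and Tubb2a were 3.07-fold, 2.44-fold, 2.35-fold, 2.26-fold and 2.38-fold higher in the spleen for ICOS WT. Of 5662 genes, 269 were at least 2-fold higher and 18 at least 2-fold lower in the LN under both labels. The lower count was 28 with TMM factors, 28 with DESeq2 factors, and 11 both without the 5% of cells with most UMIs and in thinned cells. Interferon response genes had median log2 ratios of 2.20 and 2.12, with 15 of 16 members at least 2-fold higher under each label, and proliferation genes 1.67 and 1.88, with 16 and 17 of 17. The medians were 1.503 and 1.57 for effector Treg genes, 1.51 and 1.21 for suppressive molecules and 1.27 and 1.16 for ST2 tissue Treg and Th2-type. They were 1.15 and 0.73 for costimulatory and inhibitory receptors, 0.84 and 0.79 for IL-2 and STAT5, and 0.68 and 0.70 for Treg identity. Glycolysis (0.61 and 0.56) and oxidative phosphorylation (0.50 and 0.58) were also higher, and resting Treg (-0.50 and -0.57), FoxO and Klf2 targets (-0.25 and -0.45) and ribosomal proteins (-0.40 and -0.35) lower. Among markers of other cells the medians were 1.12 and 1.64 for the B cell list, in which Cd74 had 1.34 and 1.65 but Cd79b -0.01 and 0.19, 0.96 and 0.67 for the CD8 T and NK list, and 0.29 and -0.33 for conventional CD4 T cells. Dissociation stress genes had medians of 0.18 and -0.90. TMM factors moved the median of all genes, 0.13 and 0.13 with library totals, by -0.14 and -0.13, and DESeq2 factors by -0.15 and -0.12, and turned the direction of none of the lists named here.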

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

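The tests of explanations in this part were chosen after the results were seen, and those with equal cluster weights or thinned cells reuse settings planned earlier. The values in this paragraph stand out because the libraries labelled ICOS FC and ICOS WT differed in opposite directions in the spleen and the LN; with 1 library per group the difference between tissues was not tested. The log2 ratio in the LN minus that in the spleen was -3.39 for Fos, -3.66 for Fosb, -2.05 for Jun, -1.89 for Ppp1r15a and -1.99 for Rgs2. For list medians it was -0.72 for dissociation stress genes and 0.32 for TCR-induced early genes, whose spleen value lay at the edge of its random range.

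The median of the dissociation stress list was higher in the spleen library labelled ICOS FC and lower in the LN library labelled ICOS FC. The opposite direction does not hold for every member. In the LN, 7 of 12 intervals lay below equality and 4 above. The heat shock genes Hsp90aa1 (0.41 in the spleen and 0.38 in the LN) and Hspa8 (0.30 and 0.07) were higher under ICOS FC in both tissues. The medians in thinned cells were 0.47 and -0.25, so the directions do not rest on the greater weight of cells with many UMIs. The ratios were already divided by library totals, so thinning cannot decide further on a difference in depth between libraries. For handling that moved the genes alike in every cluster, the LN values cannot decide. The list's interval lay wholly above the library's -0.21 [-0.25, -0.15] in 2 of 8 clusters, cluster 4 (-0.09 [-0.13, 0.00]) and cluster 5 (0.04 [-0.13, 0.27]). The level of the list in these clusters was no higher than the library's (log2 -0.17 and -0.22 under ICOS FC). The gaps between the bounds are small, and the intervals leave out the sampling of cells. The criterion was also set after its values were seen, and the median mixes members that went both ways. In the spleen such handling stays open: the test first used, a count of signs, replaced more than once after its values were seen, gave 6 of 6 clusters with the sign of the library (5 of 8 in the LN), and the 1 of 6 clusters that lay wholly below the library's 0.51 [0.47, 0.57], cluster 5 (0.21 [0.04, 0.27]), already had a high level of the list under ICOS WT (log2 0.61 over the library), which could hide a difference. Handling that reached some clusters more than others stays open, as does a difference that goes with genotype, tissue or challenge, untested, because each group was 1 library.

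The 15 genes that differed the same way in both tissues may have a technical or genetic source apart from ICOS signalling. For these genes as a set, a different mix of the deposited clusters is argued against. The median size of their log2 ratios was 0.93 in the spleen and 0.80 in the LN with clusters weighted equally. Over all cells it was 0.99 and 0.90. At equal weights 5 of the 9 higher and 5 of the 6 lower genes still passed the rule of size in both tissues. For the others, Icos among them, a part played by the mix stays open. A chromosome segment around Icos acting on the genes it carries cannot reach the 10 of 14 genes other than Icos on other chromosomes. This follows from position alone, and effects of a segment on genes it does not carry were not tested. The 2 genes near Icos are Il1r2 (chromosome 1, 40074079 to 40125231) and Pdcd1 (94038305 to 94052553), where 0.402 would be expected within 50 Mb. For these, the segment cannot be told apart from an effect of genotype because no library separates the segment from the label. Prg4 lies farther off on chromosome 1 (150449412 to 150466165), which carries 3 of the 14 against 0.867 expected. Prg4 and AC149090.1, on an unplaced scaffold, are in neither part. A cause that scales Icos alike in all cells of a library is argued against, with a log2 ratio of 0.17 in the Foxp3-low spleen cluster. Icos was low there in both libraries, with a UMI in 15.9% and 14.8% of the cells. A cause acting only where Icos is expressed is therefore not excluded. For Med10, with -1.15 in that cluster, a cause shared by all cells of a library stays open. A genotype effect stays open as a hypothesis, and so does an exchange of the labels, which was not tested: Icos is higher where the label says deficient, and an exchange in both tissues would turn the direction of all 15 genes with respect to genotype.

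The follicular Treg-like cluster took a smaller share of the LN library labelled ICOS FC. Fewer UMIs per cell had little to act through. Median UMIs were 6591 and 6789 over all LN cells and 5391 and 5345 in the cluster. Among the upper 50% of cells by UMIs the share difference was -6.19 points (12.7% and 6.50%). Clusters drawn on genes that differ between the libraries cannot be told apart from a smaller population, because the share difference was 0.0158 points in the clusters drawn without those genes and -8.34 points in the clusters drawn without the genes that differ at equal cluster weights. The cluster matched in the former case drew only 46.2% of its cells from the deposited one. The genes left out there include the follicular markers Cxcr5, Bcl6, Tox2 and Pdcd1, which a smaller population would lower too. The clustering with -8.34 points has the opposite limit. Its equal weights use the deposited clusters, so genes that differ only through the cluster shares are kept and can redraw the deposited cluster. Neither clustering can therefore decide, and what decides between them was not tested.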

How the results depend on the processing

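The settings without doubtful clusters, the clusterings without differing genes and all settings of the overlap and LN-against-spleen counts were chosen after seeing the data. Icos kept its direction in 22 of 22 values, of which 14 stayed within the counting interval. Among named genes, 963 of 1089 spleen values and 951 of 1186 LN values stayed within it, 117 and 230 moved and 9 and 5 reversed; among lists 99 of 120 and 132 of 168 stayed, 16 and 33 moved and 5 and 3 reversed, and among cluster shares 33 of 38 and 32 of 39 stayed, 1 and 5 moved and 4 and 2 reversed. For genes and cluster shares a change of sign counts as reversed only where the interval of the reported value is clear of equality. The cause was not tested for any value below, except that a lower or higher CPM minimum or a smaller total lets more or fewer genes reach the rule. With the total without ribosomal and mitochondrial genes, 49 spleen genes were higher and 22 lower, the conventional CD4 T median was 0.081 in the spleen, and 14 and 10 genes were higher and lower in both tissues. Further members at 5 CPM moved the conventional CD4 T median, since spleen ratios shifted by a median of only 0.002. TMM and DESeq2 factors each split the spleen 36 to 9 against 30 to 13 with totals; Icos in the LN was 0.68 with each, and 28 genes with each were lower in the LN than in the spleen. In cells with a Foxp3 UMI, 69 and 34 spleen genes and 122 and 125 LN genes were higher and lower, 17 and 10 in both tissues; Icos was 1.47 and 0.68, spleen Cxcr3 0.10, Rora 0.15 and Cd74 0.36, and LN Cd8b1 0.16, Il2 0.26 and the ST2 list -0.068. A minimum of 5 CPM gave 90 and 47 spleen genes and 168 and 193 LN genes, and a minimum of 50 CPM gave 11 and 7, and 26 and 23. In thinned cells 20 spleen genes and 133 LN genes were lower, 10 in both tissues, and 11 lower in the LN than in the spleen; spleen Mki67 was -0.20, Ube2c -0.029 and proliferation -0.065, and LN Klrg1 -0.20 and the ST2 list -0.13. Without the Foxp3-low cluster 20 spleen genes were lower. As the mean of each cell's CPM, Icos was 1.12 in the spleen and 0.69 in the LN, spleen Mki67 -0.043, Ube2c -0.21 and proliferation -0.047, and the LN ST2 list -0.0044. Without the 5% of cells with most UMIs, spleen Ube2c was -0.32, Top2a -0.11, TCR-induced early genes 0.015 and proliferation -0.068, LN Icos 0.69, and 11 genes were lower in the LN than in the spleen. With clusters weighted equally LN Icos was 0.51, Klrg1 -0.017, and 5 genes were higher in both tissues. In cells under 5% mitochondrial counts LN Il2 was 0.065 and the share difference of spleen cluster 1 was 3.39 points. Clustered without Icos, the share difference was 2.93 points for spleen cluster 0 and 3.22 for LN cluster 1, beside -2.43 and -2.26 as deposited. Clustered without differing genes it was 2.48 for spleen cluster 4 (-3.68 as deposited) and -2.12, 2.11, 0.0158 and 0.367 for LN clusters 0, 1, 2 and 4 (5.29, -2.26, -9.91 and 3.23 as deposited). Clustered without the genes differing at equal cluster weights it was 3.70 and -0.0468 for spleen clusters 0 and 1 (-2.43 and 1.64 as deposited) and 3.88 and -2.81 for LN clusters 1 and 5 (-2.26 and -1.24 as deposited). Some deposited clusters had no counterpart in a new clustering and gave no value there. Counterparts also held cells of other clusters. Without Icos, that of spleen cluster 0 drew 69.6% of its cells from the deposited cluster, and that of LN cluster 1 drew 60.6%. The labels give no replicate numbers that pair libraries, and a fit with tissue as a block was not run. Depth limits the rare transcripts: 3 counts stand for 0.110 CPM in the spleen library labelled ICOS WT and 0.199 CPM in the LN library labelled ICOS WT, so list members under 5 CPM were given no ratio, and in LN cluster 6, at 1959 median UMIs, Med10 had an interval from -1.30 to 0.85.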

Other observations

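The genes in this part were chosen after their values were seen, and nothing here was tested. Within clusters of the spleen, the log2 ratio of Prg4 was 3.07 [2.37, 3.86] in the follicular Treg-like cluster 1 and 1.97 [1.59, 2.36] in the effector Treg-like cluster 2, and 0.50 [0.16, 0.85] and -0.12 [-0.75, 0.53] in cluster 0 and the resting Treg-like cluster 3. In the LN, Prg4 had 2.66 [2.02, 3.34] in the follicular Treg-like cluster 2, 1.55 [1.29, 1.81] in the effector Treg-like cluster 0 and 0.24 [-0.22, 0.69] in the resting Treg-like cluster 1. Lag3 was at 32.6 and 83.3 CPM in LN cluster 2 (1.36 [0.95, 1.77]) and at 101 and 131 CPM in LN cluster 0 (0.37 [0.20, 0.54]). Il1r2, the IL-1 decoy receptor, was at 21.6 and 129 CPM in LN cluster 4 (2.58 [2.16, 3.03]) and at 40.2 and 46.3 CPM in LN cluster 2 (0.20 [-0.26, 0.65]). Ccl5 was at 20.8 and 110.5 CPM in LN cluster 0 (2.41 [2.09, 2.74]), beside a Gzmb ratio of -1.71 summed over the same cluster.

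Mki67, the marker of dividing cells, differed between the labels by cluster in the LN. It was at 3.74 and 83.0 CPM in cluster 3 (4 and 205 UMIs, 4.47 [3.09, 6.36]), at 4.49 and 21.4 CPM in the resting Treg-like cluster 1 (2.25 [1.37, 3.24]) and at 30.2 and 114 CPM in the follicular Treg-like cluster 2 (1.92 [1.53, 2.32]). In the effector Treg-like cluster 0 it was at 52.2 and 77.4 CPM (0.57 [0.34, 0.80]) and in cluster 4, whose cells hold many UMIs, at 64.3 and 87.7 CPM (0.45 [0.16, 0.74]). In the CD8 T and NK-like cluster 7, at 102 and 115 CPM, the interval spanned equality (0.17 [-0.39, 0.72]), and in cluster 6, whose cells hold few UMIs, Mki67 was lower, at 326 and 211 CPM (-0.62 [-1.25, -0.03]). These intervals treat each UMI as independent. How many cells held the Mki67 UMIs of a cluster, such as the 4 and 205 of cluster 3, was not counted. Cluster 3 held 7.22% and 14.2% of the cells and had no counterpart in any new clustering. Whether like cells were placed in it under both labels is therefore not known. For cluster 1 the share difference turned from -2.26 points to 3.22, 2.11 and 3.88 in the new clusterings. Its counterparts kept 92.5%, 92.6% and 90.5% of its cells but drew only 60.6%, 59.7% and 59.5% of their own cells from it. Cells of other clusters can therefore turn the sign, and whether like cells were placed in cluster 1 under both labels is not settled by it. The placing of like cells is also in doubt for cluster 2, at -9.91 points as deposited and -10.0, 0.0158 and -8.34 in the new clusterings. Over all LN cells a Mki67 UMI was seen in 10.3% and 10.6%. In the spleen Mki67 was at 5.47 and 27.5 CPM in cluster 5 (2.33 [1.28, 3.54]) and at 24.6 and 20.4 CPM in the effector Treg-like cluster 2 (-0.27 [-0.69, 0.15]).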
